A study of Mus musculus with 15 samples.

How the data were processed

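The series profiled repeat-derived RNA and DNA methylation in the testes of C57BL/6 mice lacking MIWI2 or MILI, which are PIWI proteins that bind piRNAs in male germ cells. There were 15 libraries in 11 groups. Small RNA of 19 to 30 nt was sequenced from total testis at embryonic day 16.5 (E16.5) and postnatal day 10 (P10), with 1 Miwi2 heterozygous (HET) and 1 Miwi2 knockout (KO) library at each age. Poly(A)+ RNA was sequenced from total testis of 2 heterozygous controls at E16.5, and at P10 of 1 Miwi2 HET, 1 Miwi2 KO, 2 Mili HET and 3 Mili KO samples. Bisulphite sequencing was done on P10 germ cells sorted magnetically with an antibody to EpCAM, with 1 library titled Miwi2 HET and 1 titled Miwi2 KO. The title and source of that KO library say KO while its genotype field says HET. The title was followed here, and the library is called the library titled KO. The labels state that embryonic testes were pooled by genotype from embryos of several mothers, and that P10 samples came from single animals or littermates.

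The authors aligned reads to mm10, and the submitters' processing notes name Bowtie 0.12.7, Bowtie2 2.2.2, Trim Galore and Bismark without giving the role of each. Each of the 13 RNA and small RNA tables lists 5147736 annotated repeat copies. The deposited tables give each copy a value in RPKM and a value in expected counts, with reads of several places shared among them, so that most counts are not whole numbers. Dividing the counts by copy length and RPKM gave back a fixed library total for each table, which is used below as the authors' library total. The tables hold no strand, read length or unique-alignment columns and no gene values, so that piRNAs were not separated from other small RNA, sense was not separated from antisense, and neither cell-type markers nor the Miwi2 and Mili transcripts were measured here. The deposited methylation tables give, per LINE or LTR copy, counts of CpG sites, counts of methylated and of all reads over them, and the methylation level as a fraction. These tables have 1134051 entries. Of these, 1072382 are whole copies and 61669 are regions of at most 500 bp at the 5′ ends of LINE copies, which overlap the whole copies and were kept apart.

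The authors' library totals were 13.6 and 14.3 M (mega) reads for small RNA of the E16.5 HET and KO libraries, and 11.8 and 0.903 M for the P10 HET and KO libraries. For poly(A)+ RNA they were 11.3 and 14.2 M (E16.5 control replicates 1 and 2), 8.63 M (Miwi2 HET), 13.1 M (Miwi2 KO), 34.9 and 29.4 M (Mili HET replicates 1 and 2) and 34.0, 16.5 and 23.4 M (Mili KO replicates 1 to 3). The methylation tables held 12.2 and 11.5 M CpG calls over whole copies in the HET library and the library titled KO, or 5.09 and 4.82 calls per site. Every one of the CpG sites listed for the library titled KO had reads, against 93.6% in the HET library.

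Counts were summed over all copies of each subfamily, as named by RepeatMasker, and rounded. Replicated comparisons were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM normalization over subfamilies, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. These were Mili KO against Mili HET, the Mili effect minus the Miwi2 effect at P10, and E16.5 against P10 controls. In the second of these, the single Miwi2 libraries were assumed to vary like the Mili libraries. Single L1 and LTR copies of at least 5000 bp were tested in the same way for Mili. The SE given with an edgeR log2 fold was derived from the test, as the absolute log2 fold divided by the square root of its F statistic. Of 17 repeat lists, those with at least 3 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided). The lists cover young, older and ancient L1, L2 and CR1, IAP, ETn and MusD, MMERVK10C with RLTR10, MERVL with MT2, a mixed ERV1 and ERVK group, MaLR, B1, B2, B4 with ID, MIR, DNA transposons, satellites and structural RNA. The mixed ERV1 and ERVK list was meant to hold gammaretrovirus-like ERV1 elements, but its name pattern was too wide. Of its 60 subfamilies 28 are annotated as ERV1 and 32 as ERVK, RLTR10 among them, so its values do not describe ERV1 alone.

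Comparisons of 1 library with 1 library were not tested. For these the fold of KO over HET was taken from shares of all repeat counts (after TMM for poly(A)+ RNA) with a 95% interval from exact (Clopper-Pearson) bounds, shares were given with Wilson intervals, subfamilies with at least 500 counts over both libraries were used, and simple and low-complexity repeats were left out. A change was described where it reached 2-fold. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and they do not cover variation between animals. Methylation was the percentage of methylated CpG calls over copies with at least 5 calls in both libraries. Each copy was compared between both libraries with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment, which compares the libraries and not the genotypes. The methylation intervals and this test treat CpG calls as independent, although neighbouring sites can be called from the same read. The intervals may therefore be too narrow and the calls too many. Correlations across subfamilies used 100000 permutations. Random lists of the same size, matched on counts, were drawn 10000 times.

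The named features follow a rule. The first part takes members of the young L1, IAP and ETn/MusD lists with at least 500 counts, up to 8 per list by counts. The second part takes the 5 largest rises and the 5 largest falls, among features past the threshold whose mutant libraries all lay on one side of the controls, or, in untested comparisons, among subfamilies with at least 500 counts. For copies it takes the 5 largest rises and falls past the threshold, and for methylation it ranks subfamilies with at least 500 calls in each library. The lists, tests, named-feature rule and most alternatives were set before the data were examined. Genes at named copies were looked up in RefSeq gene bounds of the same assembly.

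The alternatives were DESeq2 1.42.0, no TMM, no filter, transposon classes only, leaving out each replicate, a replicate block, copies from 1000 bp, camera with an estimated correlation, fry, a minimum of 100 counts, scaling by structural RNA, and for methylation 1 or 10 calls per copy, a mean over copies and limits on copy length. Others were added after seeing the data: the authors' library totals, subsets of libraries, a list limited to the annotated ERV1 family, leaving out the copy with the most counts of each subfamily, copies with every CpG site covered in both libraries, the 5′ ends, and the comparison with random lists. RNA counts were simulated at the same depth, but with features drawn independently at a common dispersion, that of the subfamilies also for copies. Features that vary more are recovered less often than these rates say: L1Md_T, with a measured log2 fold of 1.04 (SE 0.35), did not pass. On the simulated counts, the subfamily test of Mili KO against HET recovered 84.7% of 2-fold changes and 100% of 4-fold changes, with 4.74% false calls. The difference of effects recovered 16.2% and 80.6%, and the age comparison 23.4% and 84.5%. The test of single copies recovered 45.5% and 96.6%. The methylation test recovered 21.1% of simulated changes. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for the rest.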

Results

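Repeat-derived RNA and CpG methylation were measured in mouse testis at E16.5, when fetal germ cells acquire DNA methylation, and at P10, in animals lacking the PIWI proteins MIWI2 or MILI and in heterozygous controls. Mili had replicates in both genotypes (2 HET, 3 KO) for poly(A)+ RNA, whereas every Miwi2 comparison rested on 1 HET and 1 KO library. Repeats took 33.2% and 31.7% of the small RNA reads at E16.5 (HET and KO) and 12.6% and 13.2% at P10. They took 16.9% and 15.8% of the poly(A)+ reads of the Miwi2 HET and KO libraries, but between 5.40% and 7.56% in the Mili libraries, which belong to another series of library codes. Differences between the Mili and Miwi2 animals therefore cannot be told apart from a difference between library series.

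Loss of Mili was followed at P10 by a rise of intracisternal A particle (IAP) RNA, a long terminal repeat (LTR) retrotransposon with active mouse copies. IAPEz-int, the internal part of the element, went from 8827 ± 3432 to 62435 ± 4756 CPM (counts scaled to a common repeat total, mean ± SD, n = 2 HET and 3 KO), a log2 fold change of 2.82 (SE 0.26, edgeR adjusted p = 0.0243). The IAP internal sequence IAPA_MM-int rose by 3.18 (SE 0.40, adjusted p = 0.0310) and the IAP LTR IAPLTR1_Mm by 2.94 (SE 0.30, adjusted p = 0.0243). IAPLTR2_Mm, IAPLTR2a and IAPLTR1a_Mm rose by 1.42, 1.27 and 1.05. Outside the IAP elements, the gammaretrovirus-like MMERGLN_LTR (1.67) and MMERGLN-int (0.95) rose. All 3 KO libraries lay above both HET libraries for each of these 8 subfamilies. These values are scaled to repeat counts of total testis. With no gene values for cell-type markers, a difference in the mix of testis cells cannot be told apart from one within germ cells.

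Of 1182 subfamilies tested in the Mili comparison, edgeR called 8 higher and 0 lower, 35 had an unadjusted p under 0.05, and DESeq2 called 10 higher and 0 lower. In the IAP list 6 of 25 members were higher, 0 were lower and 19 did not pass, and 7 were higher when adjusted over the list alone. Among the members that did not pass were IAPEy-int (log2 fold 1.01, SE 0.45) and IAPEY4_I-int (0.08, SE 0.28). None of the 8 subfamilies of the young L1 list, a group of LINE elements, passed. L1Md_Gf had a log2 fold of 1.11 (SE 0.30, adjusted p = 0.923), L1Md_T 1.04 (SE 0.35, adjusted p = 0.999) and L1Md_A 0.49 (SE 0.22, adjusted p = 0.999), although all 3 KO libraries lay above both HET libraries for L1Md_Gf and L1Md_T. The 10 ETn and MusD subfamilies, LTR elements related to IAP, had a median of 0.06 and 0 calls, and MMETn-int was at 0.56 (SE 0.37). Of the 15 MMERVK10C and RLTR10 subfamilies 0 passed over all subfamilies and 1 over the list alone. In the mixed ERV1 and ERVK list 2 of 54 passed, the MMERGLN subfamilies named above.

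**Figure D1:**
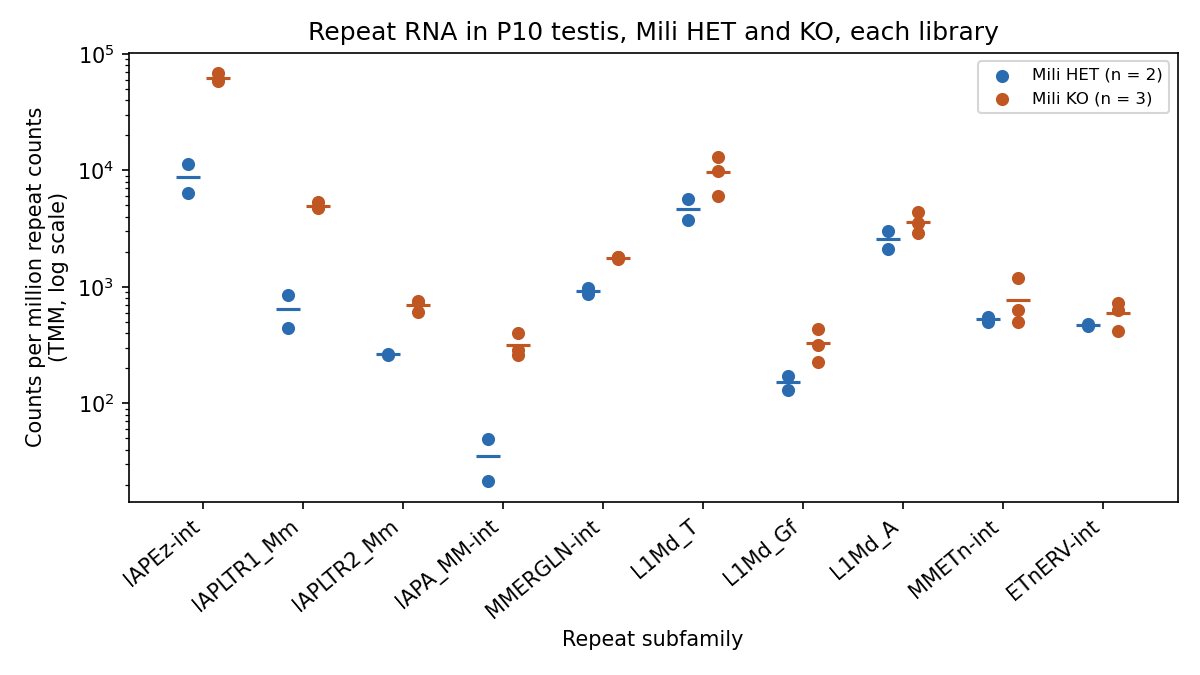
CPM of repeat counts (log axis) of 10 repeat subfamilies in P10 testis for each Mili HET (n = 2) and Mili KO (n = 3) library, with horizontal bars at the group means. The KO libraries of IAPEz-int sit between 58913 and 67845, above the HET libraries at 11254 and 6401.

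As lists, IAP (camera adjusted p = 6.6e-41, median log2 fold 0.56, 24 of 25 members positive), young L1 (adjusted p = 0.000476, median 0.35, 7 of 8 positive) and MMERVK10C (adjusted p = 0.000535, median 0.23, 11 of 15 positive) were shifted upwards relative to other repeats. With an estimated correlation only IAP passed, with adjusted p = 0.0101, while young L1 and MMERVK10C had adjusted p = 0.787. Without Mili HET replicate 1 the latter had adjusted p = 0.705 and 0.877. The other 14 lists had adjusted p from 0.182 (mixed ERV1/ERVK and DNA transposons) to 0.881 (structural RNA). Limited to its 26 tested members of the annotated ERV1 family, the mixed list had adjusted p = 0.0933. Their median log2 folds were 0.04 for older mouse L1, -0.01 for ancient L1, -0.04 for L2 and CR1, 0.06 for ETn/MusD, -0.03 for MERVL, 0.03 for mixed ERV1/ERVK, 0.02 for MaLR, -0.01 for B1, -0.02 for each of B2, B4/ID and MIR, -0.03 for DNA transposons, -0.09 for satellites and -0.01 for structural RNA. The count of 8 subfamilies fell to 5 without Mili HET replicate 1, to 2 without HET replicate 2, and to 0 without KO replicate 1, 2 or 3. The IAPEz-int fold stayed between 2.45 (without HET replicate 2) and 3.28 (without HET replicate 1), with adjusted p = 0.0963, 0.0973 and 0.165 without KO replicates 1, 2 and 3. The IAP list stayed shifted upwards each time in camera with the preset correlation, which compares subfamilies with one another and does not measure spread between animals. Over all libraries fry gave IAP an adjusted p of 0.00401, and neither fry nor the estimated correlation was rerun without a library. IAP took 7.38%, 7.66% and 8.16% of repeat counts in the KO libraries against 2.21% and 1.59% in HET. The count was 3 with the authors' library totals. Over all tested subfamilies (Pearson r of log CPM), HET replicate 1 was closer to KO replicate 1 (0.991) than to HET replicate 2 (0.977), which was itself closest to KO replicate 2 (0.989).

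Counts were also tested at single near full-length copies. Reads that match near-identical copies are shared among them in the deposited counts, so these copies rise together and the numbers do not show how many loci were active. The test estimates spread jointly over the tested copies, of which 834 of 1181 were IAPEz-int. An L1Md_F2 copy on chromosome 15 passed (edgeR adjusted p = 0.000304) although its HET libraries, at 2.70 and 25.1 CPM, lay on either side of all KO libraries. The p-values and counts of calls for copies are therefore a poor measure of spread between animals. Copies could also pass the low-count filter through the KO libraries alone. The shares and medians below therefore describe a set chosen partly by the rise itself, and are not rates among annotated copies. Without that filter, 965 of 15914 copies were higher and 7 lower. Of 1181 tested copies of at least 5000 bp (18367 annotated), 981 were higher and 5 lower in Mili KO. They included 833 of 834 IAPEz-int copies (median log2 fold 2.78), 79 of 80 MMERVK10C-int copies (median 1.55), 45 of 47 MMERGLN-int copies (median 2.74) and 9 of 10 MMETn-int copies (median 0.99), and among young L1 6 of 27 L1Md_F2 copies (2 lower), 1 of 15 L1_Mus1, 1 of 4 L1Md_F3, 0 of 8 L1Md_T and 0 of 1 L1Md_A copies. The largest rise was at an IAPEz-int copy on chromosome 5 (64558314 to 64564709), outside annotated genes, with a log2 fold of 3.73 (SE 0.71, adjusted p = 2.51e-07). The others were on chromosome 4 (135456165 to 135462540, within the protein-coding gene Nipal3, 3.66), chromosome 3 (104588594 to 104594993, 3.65), chromosome 9 (122402014 to 122408403, 3.61) and chromosome X (143172942 to 143179331, 3.59).

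The 5 lower copies had few counts. The largest fall was at an MMERVK10D3_I-int copy on chromosome 8 (82748811 to 82754948, overlapping the pseudogene Gm9655) at -1.49 (SE 0.28), with every KO library below both HET libraries. In the other 4 the KO and HET libraries overlapped. An L1Md_F2 copy on chromosome 15 (19297130 to 19303163) was at -1.10 with HET libraries at 2.70 and 25.1 CPM, and at 1.33 without HET replicate 2. The RLTR6-int copy on chromosome 2 (181919839 to 181927548) was at -0.68, and at 0.25 without HET replicate 1. The MMERVK10D3_I-int copy on chromosome 7 (43235521 to 43241627) was at -0.62, and the L1Md_F2 copy on chromosome 10 (81731449 to 81737629) at -0.54. Without HET replicate 2 they were at 0.09 and 0.39.

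Poly(A)+ repeat RNA of P10 testis was also compared between 1 Miwi2 KO and 1 Miwi2 HET library. Of 443 subfamilies, 3 were at least 2-fold higher in the KO library and 0 at least 2-fold lower. These were IAPEy-int (log2 fold 1.72, 95% interval 1.46 to 2.00), IAP-d-int (1.09, 0.84 to 1.35) and the small nuclear RNA U1 (1.21, 0.93 to 1.49). MuLV-int (0.93), the neuronal RNA BC1_Mm (0.92) and MMERVK10C-int (0.88) came next. Among young L1, L1Md_Gf was at 0.64 (0.52 to 0.76) and L1Md_T at 0.51 (0.48 to 0.53), but L1Md_A at 0.03 (interval including 0), L1Md_F2 at -0.03 and L1Md_F at -0.12. IAPEz-int was at 0.36 (0.31 to 0.40), IAPLTR2_Mm at 0.81 and IAPLTR1_Mm at 0.45. Among ETn and MusD elements, MMETn-int and ETnERV-int were both at 0.37. The lowest subfamilies were RLTR1C (-0.67), the RNA polymerase III product 7SK (-0.64) and the DNA transposons Tigger6a (-0.60), Kanga2_a (-0.58) and Tigger17a (-0.55).

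By list, the Miwi2 KO over HET log2 fold of poly(A)+ RNA was 0.41 for MMERVK10C, 0.23 for IAP, 0.21 for satellites, 0.20 for ETn/MusD, 0.13 for young L1, 0.06 for mixed ERV1/ERVK and 0.04 for DNA transposons. It was -0.01 for ancient L1, 0.00 for B2, -0.02 for MERVL and L2 with CR1, -0.03 for B1 and MIR, -0.05 for B4/ID, -0.06 for older mouse L1, -0.07 for MaLR and -0.10 for structural RNA. With the authors' library totals young L1 was at 0.0390, mixed ERV1/ERVK at -0.03 and DNA transposons at -0.05, and without TMM B2 was also at 0.00. The median IAP fold (0.34) exceeded that of 99.99% of random lists, and the median young L1 fold (0.00) that of 83.9%. Structural RNA lay as far out, at percentile 100, with a median fold of 0.23 although its summed counts were at -0.10. DNA transposons lay at percentile 98.4 and satellites at 97.6, and at the other end MaLR at 0.04 and older mouse L1 at 3.84. MMERVK10C, the highest list by summed counts, had a median fold of only 0.02, at percentile 58.0. With a minimum of 100 counts, 15 subfamilies differed 2-fold.

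Whether the Mili effect differed from the Miwi2 effect was tested directly, since the study set the 2 genes side by side. The IAPEz-int difference was 2.48 (log2, SE 0.43, unadjusted p = 0.00111, edgeR adjusted p = 0.587), with a Mili effect of 2.83 and a Miwi2 effect of 0.35. The IAPLTR1_Mm difference was 2.50 (SE 0.50, adjusted p = 0.587), IAPLTR1a_Mm 1.01 (SE 0.23) and MMERGLN_LTR 1.67 (SE 0.34). L1Md_T was at 0.55 (SE 0.64), L1Md_Gf at 0.48 (SE 0.54), L1Md_A at 0.46 (SE 0.42) and MMETn-int at 0.20 (SE 0.65). Of 1288 subfamilies, 0 passed, 88 had an unadjusted p under 0.05, and DESeq2 called 2. Adjusted over the list alone, 3 of the 25 IAP members passed (IAPEz-int, IAPLTR1_Mm and IAPLTR1a_Mm), and 0 of the young L1 and 0 of the ETn/MusD members. These tests assume that the single Miwi2 HET and KO libraries vary like the Mili libraries of the other code series, which could not be checked. The count was 2 without Mili HET replicate 1 or 2.

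To describe which repeats were transcribed when embryonic small RNA was profiled, E16.5 controls (n = 2) were compared with P10 controls (n = 3). The named IAP-related sequences IAP1-MM_I-int (-1.92, SE 0.47, adjusted p = 0.297) and IAPLTR3-int (-1.51, SE 0.34, adjusted p = 0.297) and the ETn-related ETnERV3-int (-1.46, SE 0.31, adjusted p = 0.297) had the lowest E16.5 over P10 values. IAPEz-int was at -0.27 (SE 0.45), L1Md_A at 0.77 (SE 0.45), L1Md_T at 0.58 (SE 0.46) and IAPLTR2_Mm at 0.69 (SE 0.19). Directions turned with the libraries and scaling: IAPEz-int was at 0.63 and L1Md_T at -0.12 within the same code series, and IAPEz-int was at 0.95 with the authors' library totals and at 0.16 without Mili HET replicate 1. Without the Miwi2 HET library L1Md_A (1.26), L1Md_T (1.08) and IAPLTR2_Mm (0.65) passed, with adjusted p = 0.00868, 0.0156 and 0.0188. Of 1256 subfamilies 0 passed with edgeR, 166 had an unadjusted p under 0.05, and DESeq2 called 8 higher and 54 lower. Without the Miwi2 HET library, the only P10 control of the same code series, 220 were higher and 284 lower at E16.5, and with that library as the only P10 control, assumed to vary like the 2 E16.5 libraries, 9 were higher and 16 lower. The median log2 fold was 0.88 with the authors' library totals and 0.17 without TMM, against 0.02 with TMM. Scaled to the authors' library totals, young L1 was at 8916 CPM in the Miwi2 HET library and at 1156 and 2129 in the Mili HET libraries, so age and library series were mixed in this comparison. Structural RNA took 6.59% and 12.2% of repeat counts in the E16.5 libraries, 6.43% in the Miwi2 HET library and 1.43% and 1.45% in the Mili HET libraries, so the poly(A)+ libraries also differed in RNA without poly(A) tails, between the E16.5 replicates as well.

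In embryonic testis, where MIWI2 is present, loss of Miwi2 was accompanied by a lower share of young L1 small RNA, although the fold of the list stayed short of 2-fold. Young L1 made up 18.7% of repeat counts in the HET library (95% Wilson interval 18.6 to 18.7) and 10.3% in the KO library (10.2 to 10.3), a log2 fold of -0.86 (-0.87 to -0.86). All 8 members lay below 0 with their intervals. L1_Mm was at -1.08, L1Md_A at -0.91, L1Md_T at -0.89, L1Md_F3 at -0.88, L1Md_Gf at -0.84 and L1Md_F at -0.55. LINE elements as a class went from 26.9% to 16.7% of repeat counts and LTR elements from 44.0% to 52.3%. ETn/MusD was at 0.57 (2.90% to 4.31%), MMERVK10C at 0.52 (4.58% to 6.57%), mixed ERV1/ERVK at 0.47 and MERVL at 0.38.

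IAP, the most abundant LTR group of the named lists, made up 17.9% and 18.9% of E16.5 repeat counts (log2 fold 0.07, and -0.07 per structural RNA count). IAPEz-int was at 0.11 while its LTRs IAPLTR1_Mm and IAPLTR2_Mm were at -0.36 and -0.40. Of 537 subfamilies, ERVB4_1B-I_MM-int (1.07) and IAPLTR4_I (1.03) were at least 2-fold higher and U1 (-1.33) and L1_Mm (-1.08) at least 2-fold lower. Next to these, MMERVK10C-int was at 0.95, ETnERV-int at 0.93 and RLTR4_MM-int at 0.81. Per structural RNA count, 0 subfamilies were 2-fold higher and 6 lower. Older mouse L1 was at -0.47, ancient L1 at -0.06, L2 with CR1 at 0.08, MaLR at 0.11, B1 and B2 at -0.12, B4/ID at -0.03, MIR at -0.01, DNA transposons at 0.21, satellites at 0.01 and structural RNA at 0.14. Per structural RNA count the median subfamily was at -0.13, and L2 with CR1 (-0.06), MaLR (-0.03) and satellites (-0.13) turned negative, while B4/ID and MIR turned positive within transposon classes (0.01 and 0.03). The median young L1 fold lay below that of every one of the random lists (percentile 0), and that of ETn/MusD at percentile 98.9.

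At P10 the young L1 share of small RNA was higher in the Miwi2 KO library. It was 7.24% of repeat counts in HET (7.19 to 7.28) and 18.1% in KO (17.9 to 18.3), a log2 fold of 1.32 (1.30 to 1.34). L1Md_A was at 2.67 (2.63 to 2.71), L1Md_Gf at 1.92 (1.71 to 2.13), L1Md_T at 1.69 (1.65 to 1.73) and L1_Mm at 1.31 (1.15 to 1.47), while L1Md_F2 was at 0.41 (0.36 to 0.45). ETn/MusD was at 0.49 (0.42 to 0.57), with MMETn-int at 0.66. IAP was at -0.28 (-0.31 to -0.25; 0.06 with TMM), with IAPEz-int at -0.32 (0.02 with TMM). The KO library had 0.903 M reads against 11.8 M for HET, and the median subfamily was at -0.39, or -0.05 with TMM and -0.21 per structural RNA count.

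Of 244 subfamilies at P10, 8 were at least 2-fold higher and 8 at least 2-fold lower in the KO library. This balance rested on the scaling, with 15 higher and 1 lower (MER20) with TMM, 11 and 2 per structural RNA count, and 10 and 5 with the authors' library totals. The highest, L1M5, was at 2.77 (2.59 to 2.94), but 91.7% of its KO counts came from 1 copy on chromosome 14 (29212266 to 29212812, within the gene Cacna2d3), and without that copy it was at -0.42. The lowest were MER20 (-1.39, -2.21 to -0.73; -1.05 with TMM), URR1B (-1.22; -0.88 with TMM), MuLV-int (-1.14), ORR1D2-int (-1.14) and RLTR22_Mur (-1.07). Their KO counts were between 17.4 and 62.0. Other lists at P10 were MaLR (-0.68), B2 (-0.65), B4/ID (-0.58), MERVL (-0.48), satellites (-0.39), MIR (-0.35), MMERVK10C (-0.20, and 0.14 with TMM), structural RNA (-0.19, and 0.15 with TMM), mixed ERV1/ERVK (-0.05, and 0.29 with TMM), B1 (-0.05, 0.29 with TMM, and -0.41 without the copies with the most counts, with 14 of 15 members below 0 and a median of -0.68), DNA transposons (0.09, and -0.68 without the copies with the most counts), ancient L1 (0.11, and -0.55 without the copies with the most counts), older mouse L1 (0.18) and L2 with CR1 (0.29).

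**Figure D2:**
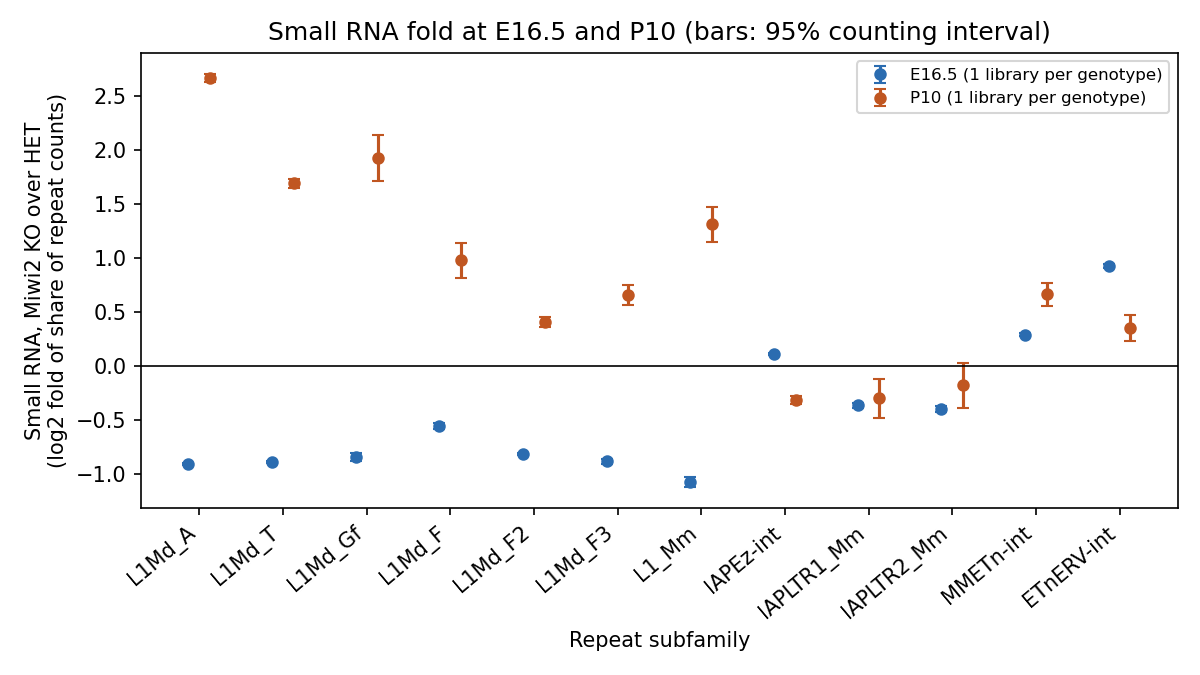
Log2 fold of the small RNA share, Miwi2 KO over HET, of 12 subfamilies at E16.5 and at P10, with 1 library per genotype and age and bars for the 95% counting interval. L1Md_A is at -0.91 at E16.5 and at 2.67 at P10, and IAPEz-int at 0.11 and -0.32, which turn to -0.03 per structural RNA count and 0.02 with TMM.

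CpG methylation of P10 germ cells was lower at young L1 and at several LTR groups in the library titled KO. Over 520209 copies, methylation was 80.7% in HET and 79.5% in the library titled KO, a difference of -1.15 points (-1.19 to -1.12). L1Md_Gf went from 83.5% to 65.0% (-18.5 points) and L1Md_T from 84.0% to 72.4% (-11.7), while L1Md_A was at -4.34 and L1Md_F2 at -2.18. Among LTRs, IAPEY_LTR was at -12.8 (-13.4 to -12.1), ERVB7_1-LTR_MM, an ETn-related LTR, at -11.7 and MMERGLN_LTR at -11.6, while IAPEz-int was at -1.11 and IAPLTR1_Mm at -3.81. By list, ETn/MusD was at -8.33, mixed ERV1/ERVK at -6.99, MMERVK10C at -6.24, IAP at -5.11 (85.3% to 80.2%) and young L1 at -3.26. Older mouse L1 was at -0.17, ancient L1 at 0.00, MaLR at 0.01 and L2 with CR1 at 0.22. Methylation was given for whole copies of 84 subfamilies only, so the lists are partial here. The MERVL list held MT2B alone (-0.19, 4605 copies), without the internal part of MERVL. ETn/MusD held ERVB7_1-LTR_MM, RLTRETN_Mm and MMETn-int, and MMERVK10C held mostly copies of RLTR10 subfamilies. The highest subfamilies were L2c (0.85, 0.53 to 1.17), ORR1D2-int (0.73), MTEa-int (0.43), MTA_Mm (0.39) and L1M2a (0.27), the last 4 with intervals including 0.

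The difference was larger at the 5′ ends of young L1, where their promoters lie. Over 13874 regions of young L1 it was -12.0 points (85.6% to 73.7%). At 5′ ends of older mouse L1 it was -2.48 points (9937 regions), and at those of ancient L1 0.38 (5303 regions, interval including 0). L1Md_Gf went from 87.2% to 61.2% (-26.0) and L1Md_T from 88.1% to 65.4% (-22.7), L1Md_F3 was at -11.0, L1Md_F2 at -9.40, L1Md_F at -6.48 and L1Md_A at -5.14. Fisher's exact test between both libraries called 1079 of 30334 of the regions lower and 26 higher, with L1Md_T at 629 lower and 2 higher of 3857. Over whole copies it called 1213 lower and 67 higher of 520209. In copies of at least 5000 bp the overall difference was -4.96 points and that of young L1 -5.81. Over copies with every CpG site covered in both libraries these were -0.58 and -1.99. There is 1 library per label, and the genotype field of the library titled KO says HET.

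**Figure D3:**
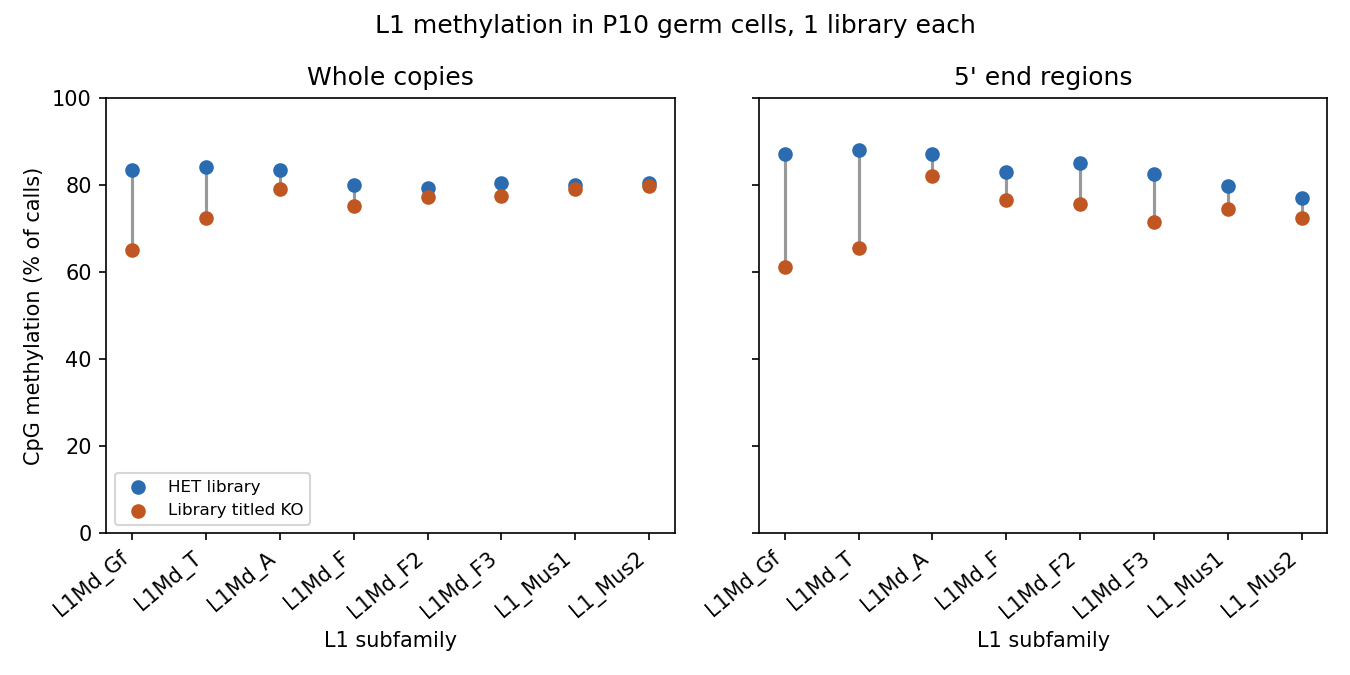
CpG methylation (percentage of calls, 1 library each) of 8 L1 subfamilies over whole copies and over 5′ end regions, with a vertical line joining the HET library to the library titled KO. L1Md_Gf drops from 87.2% to 61.2% over 5′ ends, against 83.5% to 65.0% over whole copies.

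Across subfamilies, which are not independent replicates, the methylation difference was set against the RNA folds, in 3 relations. It was correlated with the Mili RNA fold (Spearman rho -0.58, permutation p = 1e-05, the smallest they can give, adjusted p = 3e-05; Pearson r -0.43, permutation p = 0.001, adjusted p = 0.003; 79 subfamilies), and r was -0.41 without the 2 farthest subfamilies. With the Miwi2 RNA fold rho was -0.25 (permutation p = 0.03, adjusted p = 0.0451) and r -0.34 (adjusted p = 0.0178; -0.22 without the 2 farthest) over 73 subfamilies. Without the young L1, IAP and ETn/MusD lists the latter rho was -0.09 (permutation adjusted p = 0.504), and the Mili rho -0.36 (permutation adjusted p = 0.0155). With the E16.5 small RNA fold rho was -0.12 (permutation adjusted p = 0.284) and r 0.03, over 79 subfamilies. Without those lists, over 59 subfamilies, rho was -0.28 (permutation adjusted p = 0.0505) and r -0.34 (permutation adjusted p = 0.0161), so this relation depended on the lists included.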

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

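The comparison of ages and the tests of technical explanations below were all chosen after the results were seen. In Miwi2 KO over HET small RNA, the E16.5 and P10 folds had opposite signs, with counting intervals clear of 0 under all 5 scalings, for 3 of 17 lists and 8 named subfamilies. The P10 minus E16.5 log2 difference was 2.18 for young L1, 0.65 for older mouse L1 and -0.86 for MERVL. It was 3.57 for L1Md_A, 2.77 for L1Md_Gf, 2.58 for L1Md_T, 2.39 for L1_Mm, 1.54 for L1Md_F3, 1.53 for L1Md_F, 1.22 for L1Md_F2 and -1.61 for MuLV-int. The difference between ages was not tested, since each age has 1 library per genotype. No group had 4 or more samples, so no test for a single library standing apart within its group was run.

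In the E16.5 small RNA, the share of young L1 was lower in the KO library and those of ETn/MusD and MMERVK10C were higher. A passive gain of other repeats as L1 shrank would lift structural RNA as much, but the smaller of the ETn/MusD and MMERVK10C folds exceeded the structural RNA fold by 0.38. Without the copy with the most counts of each subfamily the young L1 fold was -0.87. Those copies held at most 5.50% of the counts of a young L1 subfamily (L1Md_F2), so leaving them out could hardly have undone the fold. Since reads are shared among near-identical copies, a single source locus stays open. A difference between libraries unrelated to genotype stays open: the structural RNA U1 was at -1.33, and with 1 library per genotype this cannot be told apart from an effect of Miwi2. Loss of MIWI2-dependent small RNA may be the source, and was not tested beyond this.

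In the P10 small RNA, the share of young L1 was higher in the KO library. The lower bound of the counting interval, 1.30, showed only that counting error at the low depth of that library did not account for the fold. The interval treats reads as independent molecules, so few distinct molecules or poor quality in that library stay open. Without the copy with the most counts of each subfamily the fold was 1.39. Those copies held at most 10.3% of the counts of a young L1 subfamily (L1Md_F2), so this could hardly have undone the fold. Shared reads also leave a single source locus open. A matching gain of L1 poly(A)+ RNA stays open: the young L1 poly(A)+ fold was 0.13, but with 2 times the difference between the Mili HET replicates (0.53) added it reached 1.20, above the 0.66 needed to exclude it. A difference between libraries, or in the mix of testis cells between the animals, stays open, since there is 1 library per genotype and no gene values were available for cell-type markers. The small RNA may include fragments of L1 transcripts as well as piRNAs, which the tables do not separate.

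Methylation at the 5′ ends of young L1 was lower in the library titled KO. The choice of CpG sites by coverage was argued against as the whole cause, since the difference was -10.6 points over ends with every site covered in both libraries. Lower methylation throughout that library was argued against by whole copies of MaLR and ancient L1, the larger of whose differences was 0.0113 points. At 5′ ends, ancient L1 was at 0.38 points (-0.02 to 0.77), but older mouse L1 was at -2.48. The genotype field of the library says HET, and the difference of -12.0 points cannot be told apart from one between heterozygous animals, since no spread between heterozygous libraries was available. Loss of MIWI2 may be the cause if the title is right.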

How the results depend on the processing

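The authors' library totals, the subsets of libraries, the code series, the removal of the copies with the most counts, the list limited to annotated ERV1, the 5′ ends, the random lists and the full CpG coverage were chosen after seeing the data, and the other alternatives before the data were examined. Why a value moved was not tested unless stated. The count of Mili subfamilies past the threshold (8) ranged from 0 to 5 on leaving out 1 library at a time, and was 3 with the authors' library totals, 32 with the replicate block and 0 over its 4 libraries without the block. The block rests on library numbers that need not pair animals, so that it is a hint only. The count for the Mili minus Miwi2 effect (0) was 2 with DESeq2, 5 with the block and 0 to 2 on leaving out 1 library. The age count (0) was 62 with DESeq2, 25 within the same code series, 460 with the block, 504 over its libraries without the block and 0 to 504 on leaving out 1 library, the highest without the Miwi2 HET library. The count of Mili copies was 2254 from 1000 bp. Of the repeat lists, 1 passed with an estimated correlation, 1 with fry and 1 to 4 on leaving out 1 library. With at least 100 counts, the count of 2-fold subfamilies was 15 for Miwi2 RNA, 7 for E16.5 and 68 for P10 small RNA. The young L1 fold of Miwi2 RNA was 0.0390 with the authors' library totals. That of E16.5 small RNA was -0.89 with TMM, -0.83 within transposon classes, -0.93 with the authors' totals, -1.01 per structural RNA count and -0.87 without the copies with the most counts. At P10 these were 1.66, 1.27, 1.39, 1.51 and 1.39, and L1M5 was at -0.42 without its copy with the most counts. The methylation difference over all copies was -1.29 with 10 calls per copy, -0.63 as a mean over copies, -4.96 from 5000 bp, -0.69 under 1000 bp and -0.58 with every CpG site covered. For young L1 these were -3.41, -2.46, -5.81, -1.46 and -1.99. Without the young L1, IAP and ETn/MusD lists, 1 of the 3 correlations passed by Spearman rho, and by Pearson r those with the Mili RNA fold (adjusted p = 3e-05) and the E16.5 small RNA fold (adjusted p = 0.0161) passed.

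Other named values turned direction as follows. Those with a value far from 0 included IAPEy-int in the Mili minus Miwi2 effect (-0.71), L1Md_T (0.58) and L1Md_Gf (0.66) in the age comparison, and the copy on chromosome 15 (-1.10, and 1.33 with adjusted p = 0.0360 without Mili HET replicate 2). For Mili RNA, L1_Mus1 was at 0.0123 with the authors' library totals. L1Md_F3 was at -0.0147, ETnERV3-int at -0.00683 and RLTRETN_Mm at -0.0233 without TMM. Leaving out 1 library at a time gave -0.00622 to 0.38 for L1Md_F2, -0.20 to 0.0513 for L1_Mus1, -0.0515 to 0.54 for L1Md_F, -0.33 to 0.62 for IAPEY4_I-int, -0.21 to 0.37 for ETnERV3-int, -0.00309 to 0.12 for RLTRETN_Mm and -0.46 to 0.0766 for ERVB7_2-LTR_MM. For the Mili minus Miwi2 effect, L1_Mus1 was at 0.16, ETnERV-int at 0.13 and ERVB7_2B-LTR_MM at 0.11 with the authors' library totals. ETnERV3-int was at -0.0114 with DESeq2. ETnERV3-int was at -0.0795 without TMM. ETnERV3-int was at -0.0217 without a filter. ERVB7_2B-LTR_MM was at 0.0214 with the replicate block. ERVB7_2B-LTR_MM was at 0.025 over its libraries without the block. Leaving out 1 library at a time gave -0.15 to 0.15 for L1_Mus1, -1.29 to 0.26 for IAPEy-int, -0.24 to 0.29 for ETnERV3-int, -0.26 to 0.43 for MMETn-int, -0.20 to 0.17 for ETnERV-int and -0.23 to 0.0569 for ERVB7_2B-LTR_MM. For E16.5 against P10, L1Md_F2 was at -0.21, L1Md_T at -0.12, L1Md_F3 at -0.23, L1Md_F at -0.41, L1_Mm at -0.36, L1Md_Gf at -0.24 and IAPEz-int at 0.63 within the same code series. L1_Mus1 was at 0.0601 without TMM. L1_Mus1 was at 0.73 and IAPEz-int at 0.95 with the authors' library totals. IAPLTR1a_Mm was at -0.0539, ETnERV-int at -0.13, ERVB7_2-LTR_MM at -0.19 and ERVB7_1-LTR_MM at -0.31 with the replicate block. IAPLTR1a_Mm was at -0.0587, ETnERV-int at -0.13, ERVB7_2-LTR_MM at -0.13 and ERVB7_1-LTR_MM at -0.31 over its libraries without the block. ERVB7_2-LTR_MM was at -0.0203 and ERVB7_1-LTR_MM at -0.0523 with DESeq2. ERVB7_2-LTR_MM was at -0.0289 and ERVB7_1-LTR_MM at -0.0708 without a filter. Leaving out 1 library at a time gave -0.0212 to 0.31 for L1Md_F3, -0.61 to 0.16 for IAPEz-int, -0.0587 to 0.29 for IAPLTR1a_Mm, -0.13 to 0.25 for ETnERV-int, -0.52 to 0.41 for ERVB7_2-LTR_MM and -0.31 to 0.22 for ERVB7_1-LTR_MM. The copies on chromosomes 15, 2, 7 and 10 that were lower in Mili KO ranged from -1.86 to 1.33, -1.32 to 0.25, -1.02 to 0.0856 and -1.03 to 0.39.

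Among the other values of single features and lists, the Mili subfamilies had 259 with the same result, 33 weaker and 7 stronger. The Mili copies had 86 and 30 weaker, the Mili lists 21 and 6 weaker, the Mili minus Miwi2 effect 238 and 8 stronger, and the age comparison 214 and 43 stronger. For untested values, 30 moved beyond the counting interval in Miwi2 RNA, 150 in E16.5 small RNA, 98 in P10 small RNA and 63 in methylation, with 202, 119, 159 and 127 within it. Of the correlations 5 had the same result and 1 was weaker by Spearman rho, the Pearson results being given above. Uniquely mapped reads and sense reads alone were not run, since the tables have no such columns, and pseudocounts were not used.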

Other observations

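The observations below were all chosen after the data were seen and none was tested. In control small RNA, repeats took 33.2% of reads at E16.5 and 12.6% at P10, and young L1 18.7% and 7.24% of repeat counts. B1 elements took 2.78% and 22.4%. Most of the P10 B1 counts of the subfamily B1_Mus1 came from 1 copy on chromosome 4 (119406185 to 119406286) within the gene Ccdc30, with 62.8% of the HET and 75.2% of the KO counts of the subfamily. It had 105194 counts in the HET library at P10 and 1345 at E16.5.

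At E16.5, 1 IAPEy-int copy on chromosome 7 (6616683 to 6624199, near Zim2) held 28.7% and 28.1% of the subfamily counts (HET and KO), and had 24479 and 23569 counts. The L1_Mus2 copy next to it (6612193 to 6612633) had 7362 and 2547. The copy of ERVB4_1B-I_MM-int with the most counts had 186 counts in HET and 70.0 in KO, while its subfamily was at a log2 fold of 1.07.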
